A study of Homo sapiens with 59 samples.

How the data were processed

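RNA sequencing was made from 59 libraries of HepG2 cells, an established human hepatocellular carcinoma line, harvested 24 h after treatment. Per the labels, libraries were prepared with a directional MGI kit for mRNA and sequenced as paired reads of 100 bases. The deposited table holds expected counts per gene, which the authors made with RSEM, per the submitters' processing notes. These notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3, and the human genome build GRCh38 (hg38); the gene annotation and the strand setting used for counting are not given in the sources used here. Of the nonzero values, 24.44% were not whole, so the expected counts were rounded to whole numbers before testing. The table held 60675 genes and 267 columns, of which 59 matched the samples of this series and 208 were not used. Every line of the table carried a gene identifier. Gene symbols were matched for 56558 identifiers, and GRCh38 coordinates were taken from GENCODE release 29 for 57055 identifiers.

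The libraries fell into 20 groups by their labels: 1 vehicle group, 1 wortmannin group and 6 water extracts at 3 doses each. Of these groups, 19 held 3 libraries and 1 (Pinelliae Tuber at 20 ug/mL) held 2. The series text says that samples with too little RNA were left out, and not which. The vehicle was 0.1% DMSO in the sample labels and 2% in the series text, and this difference could not be settled. The sample labels of the extract and wortmannin groups give no DMSO content. If those cells received none, a comparison with vehicle is also one of DMSO. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The first number of the code in the sample titles was 1 for vehicle and wortmannin, 2 for both gingers, 3 for Pinelliae and Scutellariae and 4 for Coptidis and Zizyphi. The meaning of this number is not stated. Every title also carries the label BatchA, vehicle and extracts alike, so the labels name a single batch. If the number nevertheless marks separate experiments, a comparison of an extract with vehicle also crosses them, whereas the top and bottom doses of an extract share the number, as do fresh and dried ginger.

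Total counts per library ranged from 21582603 to 31392069 with a median of 25834162, and 21026 to 22668 genes had a count. Replicates of a group were compared by a chi-square statistic per gene, which would be near 1 for sampling noise alone. Its mean per pair lay between 2.06 and 39.1, so no pair of libraries agreed within sampling noise. A value above 15 against both other libraries of its group marked 3 libraries as standing apart: replicate 1 of Zingiberis Rhizoma 500 ug/mL, replicate 3 of Pinelliae Tuber 100 ug/mL and replicate 1 of Zizyphi Fructus 20 ug/mL.

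Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes passed edgeR's default filter on low counts (filterByExpr with the groups), which left 16641 genes, and libraries were scaled by TMM. A single quasi-likelihood model with 20 group means gave 28 comparisons: 19 groups against vehicle, the top against the bottom dose of each of the 6 extracts, and fresh against dried ginger at each of 3 doses. The common dispersion was 0.00195, a biological coefficient of variation of 4.4%, with 39 residual degrees of freedom and a prior of 8.5. Each gene has a single spread for all groups in this model, although replicates did not agree equally well. The mean chi-square per gene was 11.2 to 39.1 between Zizyphi Fructus 20 ug/mL libraries and 2.19 to 3.77 between vehicle libraries. The p-values may therefore be too small for a group of wide spread and too large for others. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and all adjusted p-values of genes are from edgeR's quasi-likelihood test. Levels are given as CPM (counts scaled to a common library total), computed from the deposited expected counts with TMM-scaled library sizes, as mean ± SD over the libraries of a group. Fold changes and their standard errors are from the model.

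For lists of genes, limma's camera test compared the members with all other tested genes, with a preset correlation of 0.01 between members, and was repeated with an estimated correlation. Its p-values were adjusted over the 25 lists of a comparison. The lists were aryl hydrocarbon receptor targets, NRF2 targets, the ATF4 amino acid response, endoplasmic reticulum (ER) chaperones and the unfolded protein response, cholesterol synthesis and uptake, fatty acid synthesis, fatty acid oxidation and PPAR alpha targets, FOXO and insulin-repressed genes, mitotic genes, DNA replication genes, p53 targets, glycolysis and hypoxia, nuclear respiratory chain genes, mitochondrial genome transcripts, hepatocyte secreted proteins, acute phase and NF-kappaB targets, PXR and CAR targets, bile acid synthesis and transport, metallothioneins and zinc export, heat shock proteins, autophagy and lysosome, immediate early genes, cytosolic ribosomal proteins, replication-dependent histones (a sign of how RNA was selected, since these transcripts lack a poly(A) tail) and markers of other cell types. Members were counted as called over all genes tested and also adjusted over the list alone.

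The groups, comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. For wortmannin and the top doses against vehicle (7 main comparisons), the rule takes called genes with a gene symbol (no clone names, LINC or antisense genes), a mean of at least 1 CPM in the higher group and every treated library above, or below, every vehicle library, and names the 10 largest changes each way. It adds, for each list with a camera adjusted p under 0.05, the 3 called members with the largest change in the direction of the list, and 12 fixed genes, of which CYP1A1, HMOX1, ASNS, DDIT3, TRIB3, CDKN1A, IRS2, IGFBP1, TXNIP and ALB are reported. Some genes that the rule takes are not reported here. For the top against the bottom dose and fresh against dried ginger it takes the 5 largest each way, and for the middle and bottom doses against vehicle the 3 largest each way. Genes named outside the rule are marked as chosen after their values were seen.

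Against a group with no counts, a fold is a lower bound computed with a floor of 3 counts over the group. Where a group had 1 to 3 counts, the ratio is given with an exact binomial 95% interval. Such intervals and floors cover counting error only. RSEM divides reads shared between similar genes, so values of metallothioneins, AKR1C, UGT1A, CYP2D6, HSPA1A and HSPA1B, read-through genes and pseudogenes are uncertain.

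The alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0 (Wald test, default dispersion fit) and a fit of only the groups compared. Further alternatives were the replicate number as a block, an estimated correlation for camera, and leaving out each library in turn. In another, the bottom dose of the other extract with the same title number was the reference in place of vehicle. Leaving out the 3 libraries that stand apart was added later, as were the test of the difference between the dose changes of fresh and dried ginger and its alternatives, among them a fit of those 4 groups alone, and the alternatives of the genes shared by Pinelliae and Zizyphi. Where replicate numbers pair samples, the deviations of same-numbered libraries from their group means should correlate. All 3 correlations were over 0.1 only for Scutellariae Radix 500 against 20 ug/mL (0.104 to 0.236). Any pairing there is read from the values, since the labels give only shared numbers, and the block gave 8306 called genes in place of 8308.

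The procedure was tested on simulated data with 200 of 16641 genes changed. Simulated from Zizyphi Fructus 500 ug/mL against vehicle, edgeR called 24, 35, 41 and 47 of 50 genes changed by 1.2, 1.5, 2 and 4 fold, and 7 of 16421 unchanged genes. From Pinelliae Tuber 20 ug/mL with 2 libraries it called 16, 31, 44 and 46 of 50, and 8 of 16441. In the first simulation a list of 20 further genes was also raised, to test camera. Simulated counts were independent between genes, with no library standing apart and no trend with transcript length or GC content. The false calls in them therefore do not give the error rate in the real libraries.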

Results

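The transcriptome of HepG2 cells was measured 24 h after treatment with water extracts of 6 herbal medicines used for digestive complaints, to describe each medicine by the transcripts that it changes. The extracts were Zingiberis Rhizoma Recens (fresh ginger), Zingiberis Rhizoma (dried ginger), Pinelliae Tuber, Scutellariae Radix and Zizyphi Fructus, each at 500, 100 and 20 ug/mL, and Coptidis Rhizoma at 210, 42 and 8.4 ug/mL. Wortmannin at 10 uM, an inhibitor of phosphoinositide 3-kinase (PI3K), served as the positive control and DMSO as the vehicle. Each group had 3 libraries except Pinelliae Tuber 20 ug/mL with 2, and libraries held 21582603 to 31392069 counts. The first principal component carried 38.8% of the variance and the second 5.4%. Of 16641 genes tested, 11547 were called against vehicle at the top dose of Coptidis, 8354 with Scutellariae, 7654 with fresh ginger and 7058 with dried ginger. Wortmannin changed 5362 genes.

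**Figure D1:**
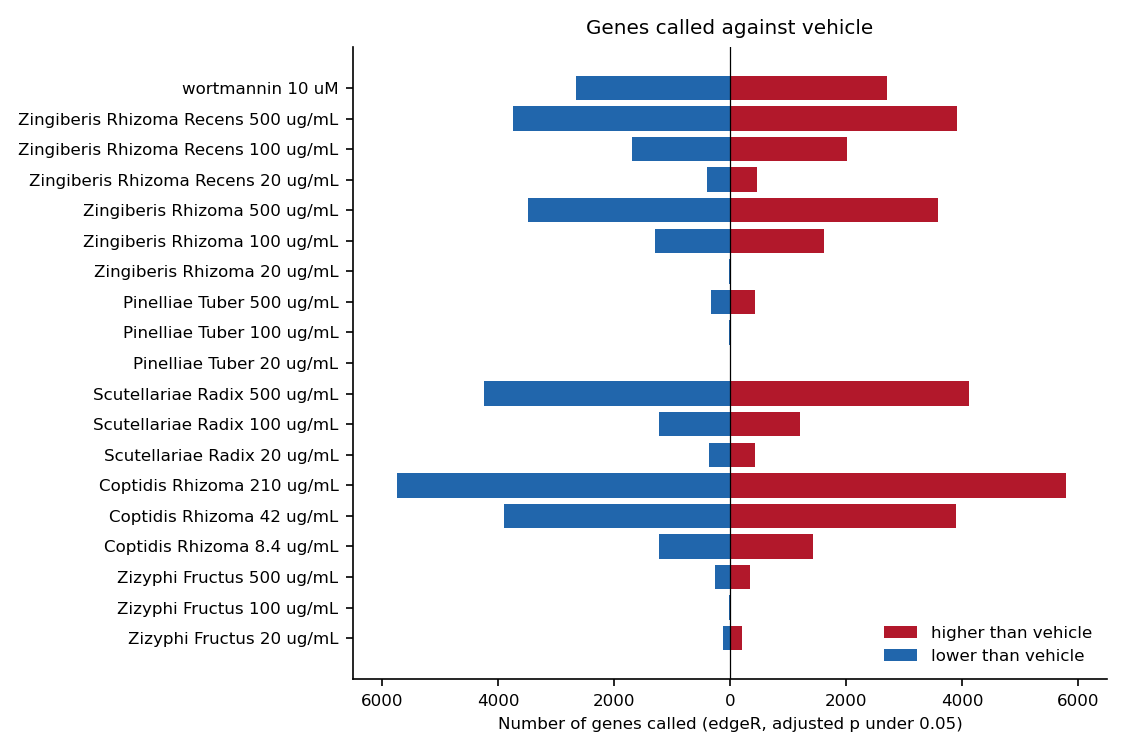
Numbers of genes called higher and lower than in vehicle (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05) for wortmannin and for each extract at each dose in ug/mL, with 3 libraries per group (2 for Pinelliae Tuber 20 ug/mL). The bar for Coptidis Rhizoma 210 ug/mL is the longest, with 5799 genes higher and 5748 lower.

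To see how the cells responded to the positive control, wortmannin was compared with vehicle. Genes that insulin normally holds down through PI3K rose. G6PC1 (ENSG00000131482, chromosome 17, 42900797 to 42913369), the glucose-releasing enzyme of the liver, rose from 2.56 ± 0.225 to 18.7 ± 2.05 CPM (SD, n = 3 each; log2 change 2.87, SE 0.115, adjusted p = 5.61e-25). IGFBP1 (ENSG00000146678, chromosome 7, 45888357 to 45893668), a secreted binder of insulin-like growth factors, rose from 39.8 ± 4.38 to 106 ± 3.04 CPM (1.42, SE 0.089, adjusted p = 6.58e-18). Every wortmannin library lay above every vehicle library for both genes. Of the 18 FOXO and insulin-repressed genes, 11 rose and 1 fell (camera adjusted p = 1.21e-08), including PIK3IP1, a negative regulator of PI3K, by 1.27 (log2). TXNIP rose by 0.36, whereas TRIB3 (0.00) and DDIT3 (-0.16) did not pass the test.

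All 20 mitotic genes fell with wortmannin (median log2 change -0.39, adjusted p = 5.82e-29), among them CDC20 (-0.68), the cyclin gene CCNB1 (-0.66) and the kinase gene PLK1 (-0.60). Of 14 immediate early genes, which growth factor signalling switches on, 8 fell and none rose (adjusted p = 1.39e-06), with IER3 at -0.93 and FOSL1 at -0.85. NRF2 targets, which handle oxidative stress, fell in 17 of 23 cases and rose in 1 (adjusted p = 2.89e-07), with AKR1B10 at -0.58 and the cystine transporter gene SLC7A11 at -0.54. The ATF4 amino acid response fell in 13 of 26 and rose in 2 (adjusted p = 1.62e-05), with ASNS, asparagine synthetase, at -0.41, and heat shock proteins fell in 8 of 14 (adjusted p = 7.59e-06), with HSP90AA1 at -0.43. The Wnt inhibitor gene DKK1 fell from 108 ± 0.894 to 46.4 ± 0.116 CPM (-1.22), and HOXD1 (-1.73) and SLC6A14 (-1.65) fell further.

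Of 19 hepatocyte secreted proteins 15 rose and 1 fell with wortmannin (median 0.25, adjusted p = 1.85e-15), with TTR at 1.02, FGA at 0.83 and APOC3 at 0.66, and the sex hormone carrier SHBG rose by 1.51. Fatty acid oxidation and PPAR alpha targets rose in 14 of 16 and fell in 2 (adjusted p = 5.25e-07), with CREB3L3 at 1.22. Cholesterol synthesis and uptake rose in 15 of 25 (adjusted p = 1.12e-06), with HMGCS1 at 0.36. PXR and CAR targets rose in 5 of 13 and fell in 1 (adjusted p = 0.00667), with the sulfotransferase SULT2A1 at 0.63.

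With an estimated correlation these calls held, and the following did not. ER chaperones fell in 9 of 18 and rose in 1 (adjusted p = 0.103 with an estimated correlation) and fatty acid synthesis rose in 7 of 14 (adjusted p = 0.0916 with an estimated correlation). DNA replication genes fell in 6 of 19 and rose in 2 (adjusted p = 0.171 with an estimated correlation), the list of metallothioneins and zinc export (7 metallothioneins and the zinc exporter SLC30A1 among the tested genes) fell in 6 of 8 (adjusted p = 0.151 with an estimated correlation), autophagy and lysosome genes rose in 8 of 19 and fell in 2 (adjusted p = 0.0502 with an estimated correlation), and bile acid genes rose in 7 of 11 and fell in 2 (adjusted p = 0.0723 with an estimated correlation). Adjusted over the list alone, the counts of these lists and those above were the same except for 16 rises in cholesterol synthesis, 8 in fatty acid synthesis, 9 in bile acid genes, 9 falls in DNA replication and 7 in metallothioneins and zinc export. Aryl hydrocarbon receptor targets had 4 members higher and 2 lower of 10 (adjusted p = 0.774), and 3 nuclear respiratory chain genes of 23 were higher and 2 lower (adjusted p = 0.741).

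**Figure D2:**
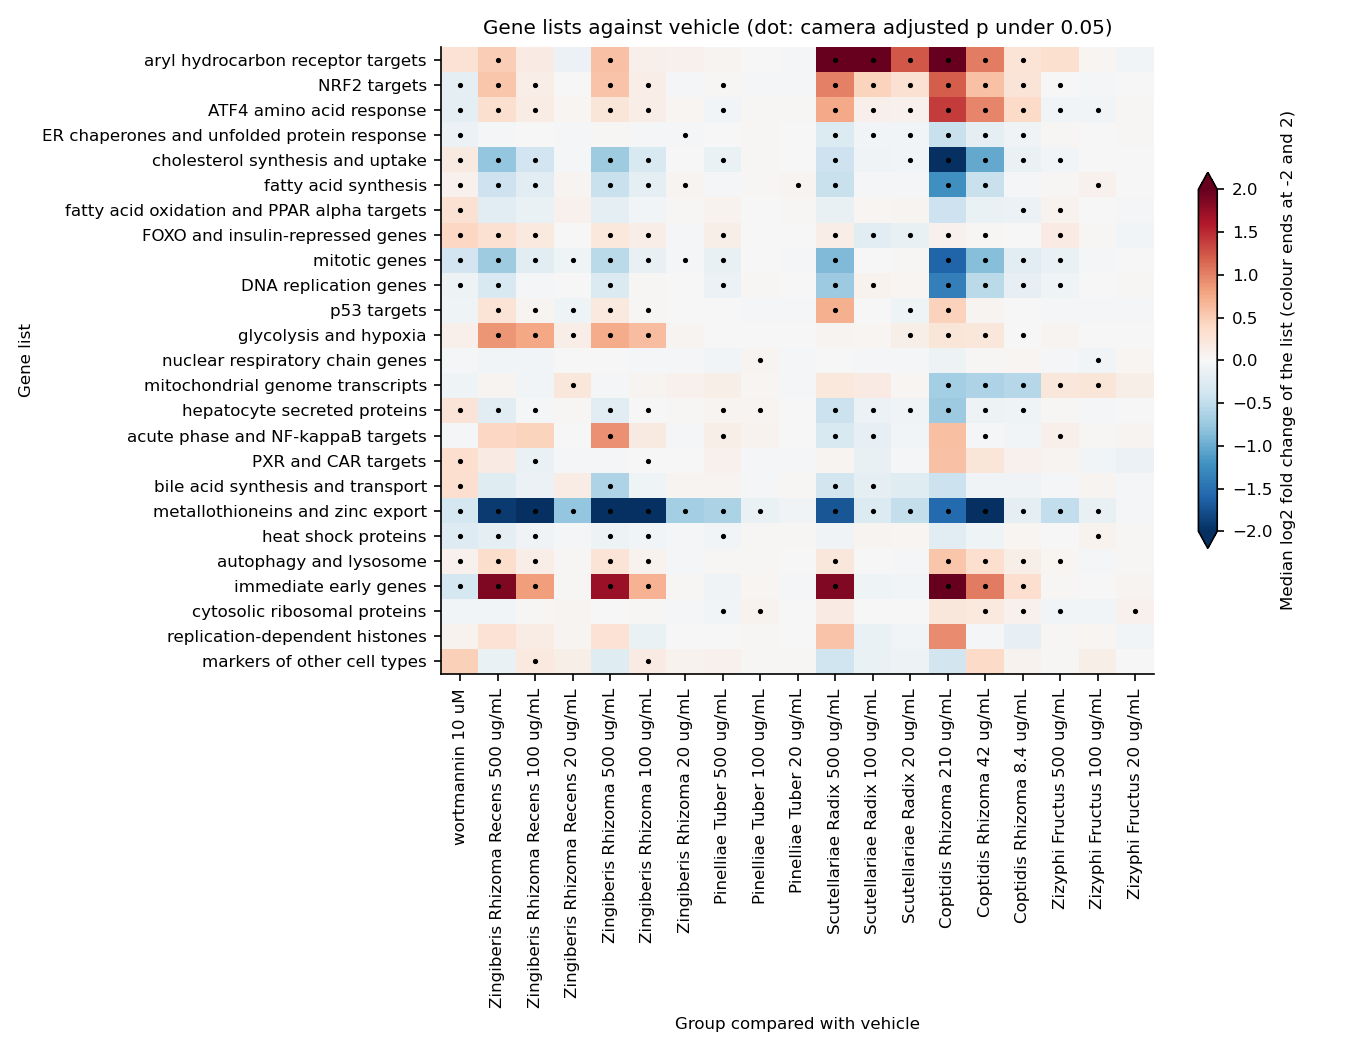
Median log2 change against vehicle of the tested members of each gene list (colour, ending at log2 values of -2 and 2) for wortmannin and each extract at each dose in ug/mL; a dot marks a camera adjusted p under 0.05 with the preset correlation. Cholesterol synthesis and mitotic genes were lower at the top doses of both gingers, Scutellariae and Coptidis.

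Both gingers were compared with vehicle to find the transcripts that fresh and dried rhizome change. At 500 ug/mL IGFBP1 rose to 862 ± 44.8 CPM with fresh ginger (log2 change 4.44) and to 678 ± 19.7 with dried ginger (4.09), from 39.8 ± 4.38 in vehicle (n = 3 each). IGFBP3 rose by 4.71 and 3.84 and the glycerol and water channel AQP3 by 3.49 and 3.08, here and below fresh ginger first. All 14 immediate early genes rose with fresh ginger (median 1.87, adjusted p = 1.22e-36) and 13 with dried ginger (1.72, adjusted p = 4.15e-41), with FOS at 4.30 and 4.15, FOSB at 3.72 and 3.70 and EGR1 at 2.73 and 2.51. CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610), the drug-metabolising enzyme that marks aryl hydrocarbon receptor activity, rose from 12.3 ± 1.13 CPM to 71.3 ± 0.354 and 73.2 ± 1.43.

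All 19 glycolysis and hypoxia genes rose with both gingers (medians 0.88 and 0.74, adjusted p = 2.5e-29 and 1.79e-29), with the carbonic anhydrase CA9 at 3.26 and 3.06, PFKFB3 at 2.25 and 1.75 and NDRG1 at 1.95 and 1.64. NRF2 targets rose in 21 of 23 and fell in 1 with fresh ginger (adjusted p = 1.19e-30) and rose in 19 and fell in 2 with dried ginger (adjusted p = 1.33e-25), with AKR1B10 at 2.14 and 1.85 and SLC7A11 at 2.11 and 1.73. The ATF4 response rose in 19 of 26 and fell in 3 (adjusted p = 9.03e-12), and rose in 17 and fell in 3 with dried ginger (adjusted p = 2.09e-08). Among its members GDF15 rose by 2.59 and 2.43 and ASNS by 1.03 and 0.61, while DDIT3 did not pass the test at 0.19 and 0.07. Of 20 p53 targets 14 rose and 3 fell with fresh ginger (adjusted p = 1.5e-07) and 13 rose and 5 fell with dried ginger (adjusted p = 2.38e-06), with the cell cycle inhibitor CDKN1A at 1.17 and 1.08.

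Cholesterol synthesis and uptake fell in 22 of 25 and rose in 1 with each ginger (medians -0.77 and -0.71, adjusted p = 1.3e-33 and 7.24e-38). HMGCS1 fell by 1.07 and 1.01 on the log2 scale. All 14 fatty acid synthesis genes fell (adjusted p = 4.32e-13 and 3.06e-16), with GPAM at -1.28 and -1.33. All 20 mitotic genes fell (medians -0.71 and -0.54, adjusted p = 1.01e-30 and 3.98e-23), with KIF20A at -1.08 and -0.88, and DNA replication genes fell in 15 of 19 and rose in 1 and 2 (adjusted p = 1.64e-08 and 2.38e-06), with MCM2 at -0.66 and -0.55. The fibrinogen chain FGA fell by 1.52 and 1.24, among 11 and 10 of 19 hepatocyte secreted proteins that fell while 3 and 4 rose (adjusted p = 1.71e-09 and 1.89e-08). Metallothioneins, which bind zinc and copper, and zinc export, a list of 7 metallothioneins and SLC30A1, fell in 7 of 8 with fresh ginger (median -1.92, adjusted p = 1.44e-13) and in all 8 members with dried ginger (-2.38, adjusted p = 2.38e-21). MT1F (ENSG00000198417, chromosome 16, 56657694 to 56660698) fell from 55.1 ± 2.55 CPM to 4.31 ± 0.429 and 4.16 ± 0.598, and MT1M was lower by a ratio of 43.5 (95% interval 14.6 to 214) and 46.9 (15.7 to 230).

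Further lists passed the test with the gingers at 500 ug/mL. Autophagy and lysosome genes rose in 15 and 14 of 19 and fell in 1 with each (adjusted p = 1.54e-07 and 1.21e-06). FOXO and insulin-repressed genes rose in 9 and 10 of 18 and fell in 2 and 3 (adjusted p = 7.31e-05 and 5.83e-05), and heat shock proteins fell in 9 and 7 of 14 and rose in 2 and 1 (adjusted p = 0.0138 and 0.0325). Aryl hydrocarbon receptor targets rose in 3 and 4 of 10 (adjusted p = 0.0173 and 0.00612), and their median with fresh ginger was 0.49, or 0.22 with members near 0 counts set at their bound. With dried ginger, bile acid genes fell in 6 of 11 and rose in 3 (adjusted p = 0.0328), with the bile acid receptor NR1H4 at -1.80. Acute phase and NF-kappaB targets rose in 8 of 13 and fell in 5 with dried ginger (adjusted p = 0.0493, and adjusted p = 0.102 with an estimated correlation), with the chemokines CXCL8 at 2.43 and CCL20 at 2.08. The other list calls of the gingers at 500 ug/mL held with an estimated correlation. Adjusted over the list alone, fresh ginger gave 16 falls in DNA replication, 5 in p53 targets, 10 in heat shock proteins and 16 rises in autophagy, and dried ginger gave 14 rises in immediate early genes, 20 in NRF2 targets, 11 falls in secreted proteins and 8 in heat shock proteins; other counts were the same. In dried ginger 500 ug/mL, replicate 1 stood apart from the other libraries (mean chi-square per gene 15.1 to 21.0).

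At 100 ug/mL the gingers changed 3701 and 2914 genes. IGFBP1 rose by 3.49 and 2.84, the lipocalin LCN15 by 3.95 and 3.19 and HAVCR1, an injury marker of kidney epithelium, by 2.86 and 2.56. Glycolysis and hypoxia genes rose in 19 and 18 of 19 (adjusted p = 1.56e-66 and 2.09e-49), adjusted over the list alone 19 with each ginger, and metallothioneins and zinc export fell in all 8 members (adjusted p = 1.34e-54 and 6.25e-72). Cholesterol synthesis fell in 21 of 25 with fresh ginger and rose in 1 (median -0.39, adjusted p = 7.88e-29), adjusted over the list alone in 22. Markers of other cell types, of which 9 of 22 were tested, rose in 3 members with each ginger (adjusted p = 0.0427 and 0.0166), adjusted over the list alone in 4 with fresh ginger while 1 fell; with dried ginger their median was 0.16, or 0.03 with members near 0 counts at their bound. The secreted proteins with dried ginger had a median of 0.01 and a mean of -0.10, and the test pointed down (adjusted p = 0.000411, and adjusted p = 0.133 with an estimated correlation).

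At 20 ug/mL metallothioneins and zinc export also fell, in 7 of 8 with fresh ginger (median -0.78, adjusted p = 8.6e-28) and in 7 of 8 with dried ginger (-0.68, adjusted p = 8.5e-45; 8 adjusted over the list alone). MT1F fell by 0.83 and 0.82 and MT1E by 0.87 and 0.75 on the log2 scale. With dried ginger the zinc importer genes SLC39A10 (0.46) and SLC39A4 (0.31) rose. With fresh ginger glycolysis and hypoxia genes rose in 3 of 19, adjusted over the list alone in 9 (adjusted p = 2.9e-07, and adjusted p = 0.137 with an estimated correlation). The counts of called genes at this dose depended on the libraries and the setting used. Leaving out a library leaves fewer to test, which alone can lower a count. Fresh ginger gave 849 genes. It gave 1798 without the 3 libraries that stand apart, none of which is in the groups compared, so through estimates shared by all libraries. Without vehicle replicate 1, 2 or 3 it gave 140, 215 and 528. Without its own replicate 1 or 3 it gave 484 and 70. Dried ginger gave 14 genes (28.6% higher), but 322 in a fit of only the 2 groups (73.6% higher), 255 with no filter on low counts (74.9% higher), 49 without the 3 libraries that stand apart (53.1% higher) and 19 with DESeq2 (42.1% higher), so which direction held more genes depended on the setting. It gave 9, 9 and 8 without vehicle replicate 1, 2 or 3 and 6 without its own replicate 3.

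**Figure D3:**
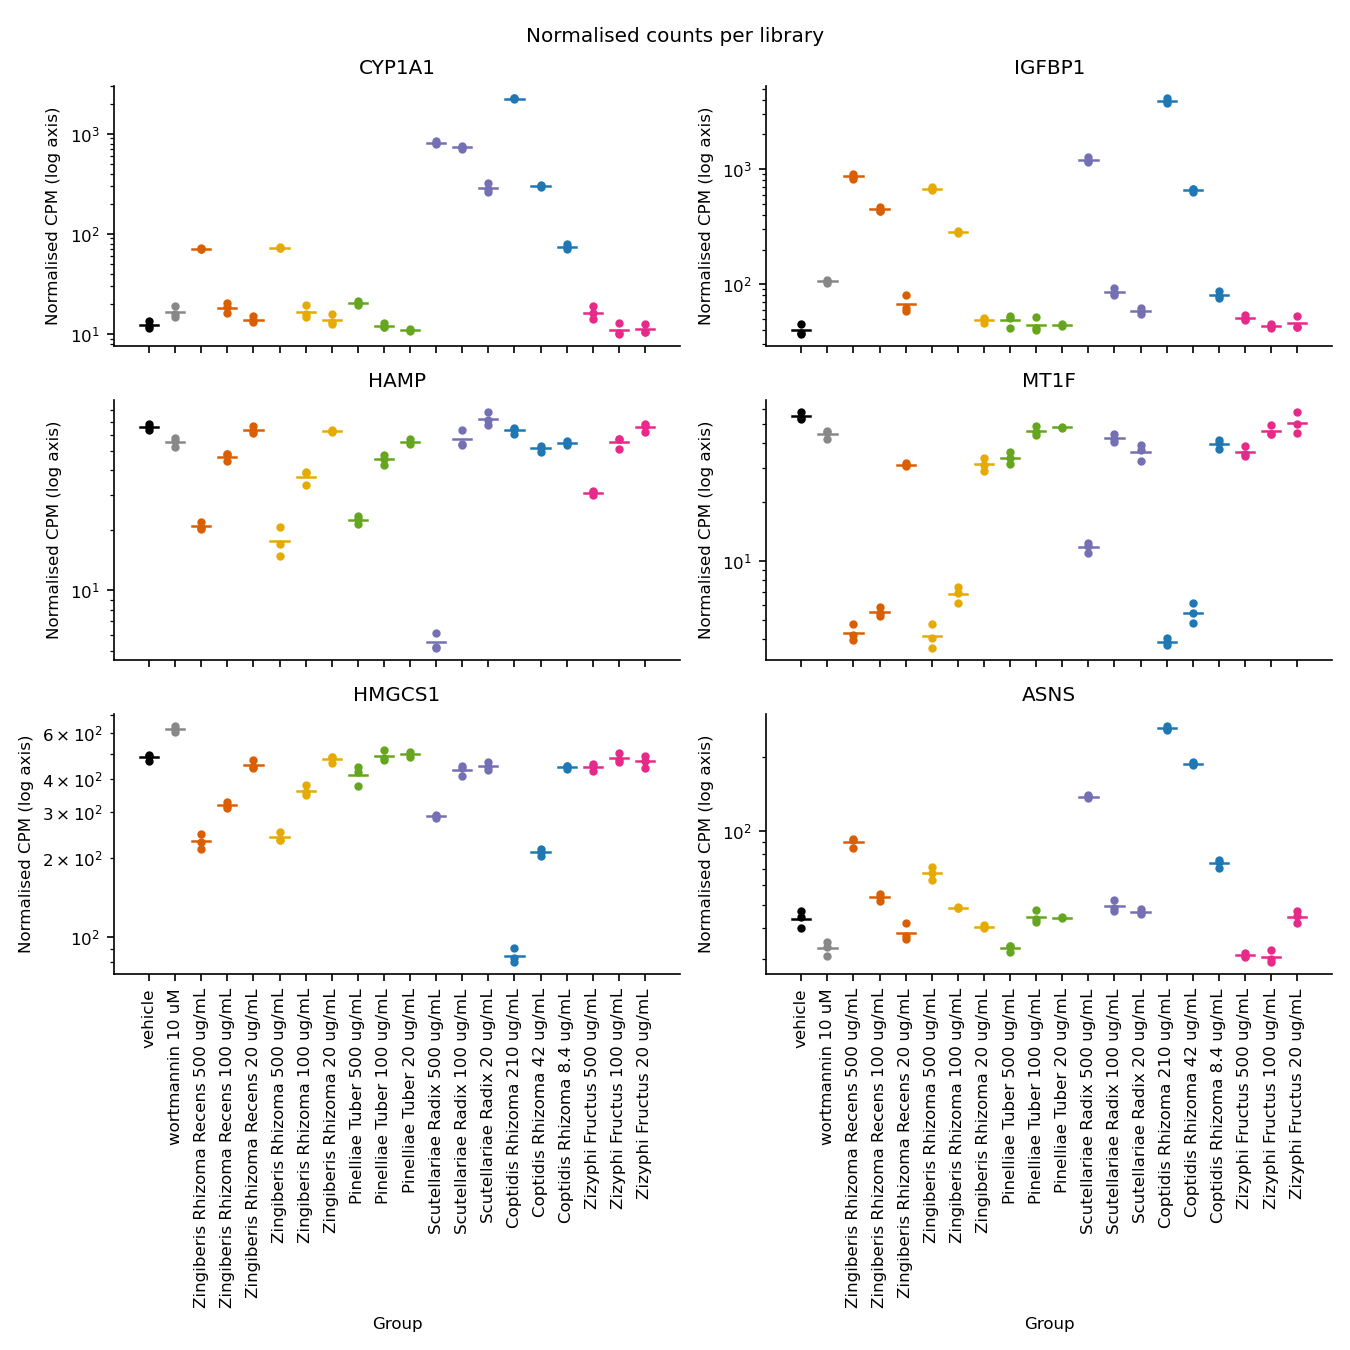
Expression in CPM (log axis) of CYP1A1, IGFBP1, HAMP, MT1F, HMGCS1 and ASNS in each library (points) with the group mean (horizontal bars), for vehicle, wortmannin and each extract by dose in ug/mL. CYP1A1 in Scutellariae Radix reached 815 ± 23.1 CPM at 500 ug/mL against 12.3 ± 1.13 in vehicle.

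To compare the rhizome in its fresh and dried forms, fresh was tested against dried ginger at each dose. At 500 ug/mL, 305 genes differed, 160 higher and 145 lower with fresh ginger, all libraries of each in the comparison carrying the same title number. Mitotic genes were lower with fresh ginger in 11 of 20 (median -0.17, adjusted p = 1.26e-24) and acute phase and NF-kappaB targets in 8 of 13 (adjusted p = 7.92e-24), whereas NRF2 targets were higher in 11 of 23 (adjusted p = 2.13e-16) and the ATF4 response in 5 of 26 (adjusted p = 5.62e-12). Metallothioneins and zinc export were higher in 2 of 8 (adjusted p = 2.77e-05). Adjusted over the list alone these counts were 15, 10, 12, 13 and 4. IGFBP3 was higher by 0.87, the matrix protease MMP3 by 0.80 and the long noncoding RNA UCA1 by 0.65, while the ubiquitin-like UBD (-0.78) and the immune surface protein CD83 (-0.97) were lower. The count was 29 (21 higher and 8 lower) in a fit of only the 2 groups, 501 (236 higher and 265 lower) with no filter on low counts, and with RLE size factors 152 were higher and 161 lower. It was 158 without dried replicate 1, which stood apart, 605 without dried replicate 2, 195 without fresh replicate 2 and 159 without fresh replicate 3.

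At 100 ug/mL, 54 genes were higher and 9 lower with fresh ginger. Glycolysis and hypoxia genes were higher in 5 of 19, adjusted over the list alone in 17 (median 0.18, adjusted p = 1.31e-35), with PFKFB3 at 0.64, and IGFBP1 (0.65), LCN15 (0.76) and CHST15 (0.65) were higher. FGA (-0.26), FGG (-0.25) and HP (-0.24) were lower. The 63 genes became 68 to 178 with RLE size factors, DESeq2, a block, no filter, a fit of only the 2 groups or the 3 libraries apart left out, and 29 or 30 without dried replicate 1 or 2 and 28 or 36 without fresh replicate 2 or 3. At 20 ug/mL 8 genes differed (7 higher). No list call at this dose held with an estimated correlation. With edgeR this count became 0 in a fit of only the 2 groups and without dried replicate 1 or 2 (1417 genes had an unadjusted p under 0.05 in all libraries and DESeq2 called 13), 3, 26 or 2 without fresh replicate 1, 2 or 3, and 2 without dried replicate 3.

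Scutellariae Radix was compared with vehicle next. CYP1A1 rose from 12.3 ± 1.13 to 815 ± 23.1 CPM at 500 ug/mL (log2 change 6.05), and by 5.90 at 100 and 4.55 at 20 ug/mL. The related CYP1A2, without counts in vehicle, was at least 17.5-fold higher at 500 and at least 32.4-fold higher at 100 ug/mL. Of 10 aryl hydrocarbon receptor targets 9 rose at 500 ug/mL (10 adjusted over the list alone; median 3.05, adjusted p = 5.64e-12), 8 at 100 (adjusted p = 5.66e-66) and 7 at 20 ug/mL (adjusted p = 9.35e-65). ALDH3A1, an aldehyde dehydrogenase of this list, rose by 3.42 at 100 and 2.53 at 20 ug/mL, and UGT1A1, which conjugates bilirubin, rose by 3.65 at 500 ug/mL. NRF2 targets rose in 22 of 23 at 500 (median 1.00, adjusted p = 1.64e-38), in 20 at 100 (adjusted p = 5.45e-69) and in 17 at 20 ug/mL (adjusted p = 5.34e-63), adjusted over the list alone in 22, 21 and 20, with SLC7A11 at 2.36 and TXNRD1 at 1.45 at the top dose.

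The top dose of Scutellariae changed 8354 genes. AQP3 rose by 5.29, the matrix protease MMP3 by 5.01, the secreted peptide gene VGF by 4.87 and IGFBP1 by 4.92, to 1200 ± 54.2 CPM. HSPA6, a heat shock protein with 3 or fewer counts in vehicle, was higher by a ratio of 239 (95% interval 81.4 to 1160). HAMP (ENSG00000105697, chromosome 19, 35280716 to 35285143), which encodes the iron hormone hepcidin, fell from 66.03 ± 2.15 to 5.50 ± 0.538 CPM (log2 change -3.59, adjusted p = 2.68e-35). The ATF4 response rose in 22 of 26 and fell in 1 (adjusted p = 1.32e-27), with ASNS at 1.65, TRIB3 at 1.14 and DDIT3 at 1.00. Of 20 p53 targets 18 rose (adjusted p = 4.38e-28), with GDF15 at 2.93 and CDKN1A at 2.38, and all 14 immediate early genes rose (adjusted p = 1.72e-36), while autophagy and lysosome genes rose in 15 of 19 and fell in 1 (adjusted p = 2.65e-06).

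All 20 mitotic genes (median -0.89, adjusted p = 1.64e-38) and all 19 DNA replication genes (-0.72, adjusted p = 9.5e-25) fell at this dose, with MKI67 at -1.26 and MCM2 at -0.98. Cholesterol synthesis fell in 22 of 25 and rose in 1 (adjusted p = 1.32e-09), and all 14 fatty acid synthesis genes fell (adjusted p = 6.62e-07). ER chaperones fell in 14 of 18 and rose in 1 (adjusted p = 3.13e-06), with PDIA4 at -0.63. Hepatocyte secreted proteins fell in 16 of 19 and rose in 1 (adjusted p = 8.31e-10), with APOH at -1.24 and HP at -1.12. Acute phase targets fell in 7 of 13 and rose in 3 (adjusted p = 0.0116), bile acid genes fell in 5 of 11 and rose in 1 (adjusted p = 0.00288), and metallothioneins and zinc export fell in 7 of 8 (adjusted p = 1e-06), with MT1F at -2.22. FOXO and insulin-repressed genes rose in 10 of 18 and fell in 3 (adjusted p = 0.00016). All of the list calls at this dose held with an estimated correlation, and adjusted over the list alone FOXO genes had 4 falls, secreted proteins 2 rises and metallothioneins and zinc export 8 falls, while the other counts were the same.

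At lower doses 2431 genes changed at 100 and 789 at 20 ug/mL, the latter 483 without vehicle replicate 1 and 410 without replicate 1 of the extract. The receptor PDGFRB (-1.56), HOXD1 (-1.46) and the potassium channel KCNJ10 (-1.43) fell at 100 ug/mL and the endothelin gene EDN1 (-1.34) fell at 20 ug/mL. Metallothioneins and zinc export fell in 7 of 8 at 20 ug/mL (adjusted p = 1.98e-11).

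Coptidis Rhizoma at 210 ug/mL gave the largest count of called genes of all groups (11547, of which 3650 changed at least 2 fold). CYP1A1 rose to 2254 ± 44.0 CPM (183-fold, log2 change 7.51), AQP3 from 3.98 ± 0.306 to 701 ± 2.28 CPM (7.46) and IGFBP1 to 3931 ± 201 CPM (6.63). CYP1A2 was at least 172-fold higher, the melanosome transport gene MLPH at least 67.9-fold higher and LRRC66 at least 45.3-fold higher, each from 0 counts in vehicle. TMEM156 was higher by a ratio of 771 (95% interval 213 to 6380) and SERPINB2 by 301 (53.7 to 11900). All 10 aryl hydrocarbon receptor targets rose (median 5.19, adjusted p = 8.88e-13), with CYP1B1 at 6.04. All 14 immediate early genes rose (median 3.34, adjusted p = 7.69e-31), with FOS at 6.62, FOSB at 6.04 and EGR1 at 4.69, and the mucin MUC5AC rose by 7.96.

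The cholesterol genes had the lowest median of the lists that fell here, -2.20, with 24 of 25 members lower and 1 higher (adjusted p = 2.25e-51). ACAT2 fell by 2.96 and MVD by 2.66 on the log2 scale. All 14 fatty acid synthesis genes fell (median -1.22, adjusted p = 3.24e-16), with the desaturase SCD at -2.02. All 20 mitotic (median -1.60, adjusted p = 1.95e-34) and 19 DNA replication genes (-1.36, adjusted p = 5.67e-29) fell, with KIF20A at -2.43 and UHRF1 at -2.09. Hepatocyte secreted proteins fell in 15 of 19 and rose in 2 (adjusted p = 1.36e-10), with FGA at -3.33, FGG at -3.19 and ALB at -0.72, and ER chaperones fell in 15 of 18 and rose in 2 (adjusted p = 1.88e-05).

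With Coptidis at 210 ug/mL the ATF4 response rose in 24 of 26 and fell in 2 (median 1.40, adjusted p = 9e-25), with ATF3 at 4.18, GDF15 at 4.11, SLC7A11 at 3.72, ASNS at 2.57 and DDIT3 at 1.71. NRF2 targets rose in 20 of 23 and fell in 2 (adjusted p = 3.09e-24), with SQSTM1 at 2.45 and SRXN1 at 2.42. Of 20 p53 targets 13 rose and 4 fell (adjusted p = 0.000142), with CDKN1A at 2.53, and autophagy and lysosome genes rose in 15 of 19 and fell in 3 (adjusted p = 3.2e-05), with GABARAPL1 at 2.18. Heat shock proteins had 6 members higher and 8 lower of 14 (adjusted p = 0.67). An estimated correlation kept these 4 rises. It ended the calls of FOXO genes, 8 higher and 7 lower of 18 (adjusted p = 0.0952 with an estimated correlation), glycolysis and hypoxia, 10 higher and 4 lower of 19 (adjusted p = 0.382 with an estimated correlation), metallothioneins and zinc export, 2 higher and 5 lower of 8 (adjusted p = 0.238 with an estimated correlation), and mitochondrial genome transcripts, 12 of 13 lower (adjusted p = 0.522 with an estimated correlation). MT1F fell by 3.82 and NDRG1 rose by 2.75, while TXNIP did not pass the test at 0.06 (it passed at 0.12 against the bottom dose of Zizyphi). Adjusted over the list alone the counts were the same except for 3 ER chaperones that rose and 6 members of metallothioneins and zinc export that fell. Nuclear respiratory chain genes had 2 members higher and 10 lower of 23 (adjusted p = 0.216) and the replication-dependent histones 7 higher and 1 lower of 12 (adjusted p = 0.233).

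At 42 ug/mL Coptidis changed 7801 genes. CYP1A1 rose by 4.61, the fucosyltransferase FUT1 by 4.19 and IGFBP1 by 4.05, and MT1F (-3.33) and MT1G (-2.98) fell. The ATF4 response rose in 24 of 26 (adjusted p = 5.59e-53), cholesterol synthesis fell in 23 of 25 and rose in 1 (median -1.03, adjusted p = 8.87e-59), all 20 mitotic genes fell (adjusted p = 2.42e-39) and 6 of 8 genes of metallothioneins and zinc export fell (adjusted p = 1.26e-11), counts that were the same adjusted over the list alone. At 8.4 ug/mL, 2656 genes changed. The ATF4 response rose in 20 of 26, adjusted over the list alone in 24 (median 0.38, adjusted p = 4.7e-52), NRF2 targets rose in 18 of 23 and fell in 1 (adjusted p = 1.03e-25), aryl hydrocarbon receptor targets rose in 5 of 10 (adjusted p = 4.58e-10) and mitotic genes fell in 17 of 20, adjusted over the list alone in 19 (adjusted p = 1.88e-18).

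Mitochondrial transcripts shifted in both directions at 8.4 ug/mL of Coptidis. MT-RNR1 (ENSG00000211459, mitochondrial genome, 648 to 1601), the small ribosomal RNA of the mitochondrion, rose from 4147 ± 170 to 41750 ± 4070 CPM (10.1-fold, log2 change 3.33, adjusted p = 1.25e-29, higher in 3 of 3 libraries), while MT-ND4 (-1.21) and MT-ND4L (-1.14), subunits of respiratory complex I, fell. Of the 13 protein-coding transcripts of this genome 4 rose and 7 fell (adjusted p = 0.000101, and adjusted p = 0.219 with an estimated correlation), 8 of them lower adjusted over the list alone. Chosen after their values were seen, MT-RNR2 rose by 2.19 and MT-ND5 (1.12), MT-ND6 (0.90), MT-CYB (0.87) and MT-ND1 (0.45) rose, whereas MT-CO1 (-0.44), MT-CO2 (-0.74), MT-CO3 (-0.95), MT-ATP6 (-0.79) and MT-ND3 (-0.84) fell. MT-RNR1 rose by 3.62 at 42 and 2.86 at 210 ug/mL. All mitochondrial genes together held 17.8 ± 1.74, 17.7 ± 0.445 and 12.4 ± 0.709% of counts at 8.4, 42 and 210 ug/mL against 9.60 ± 0.444% in vehicle, each with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow.

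**Figure D4:**
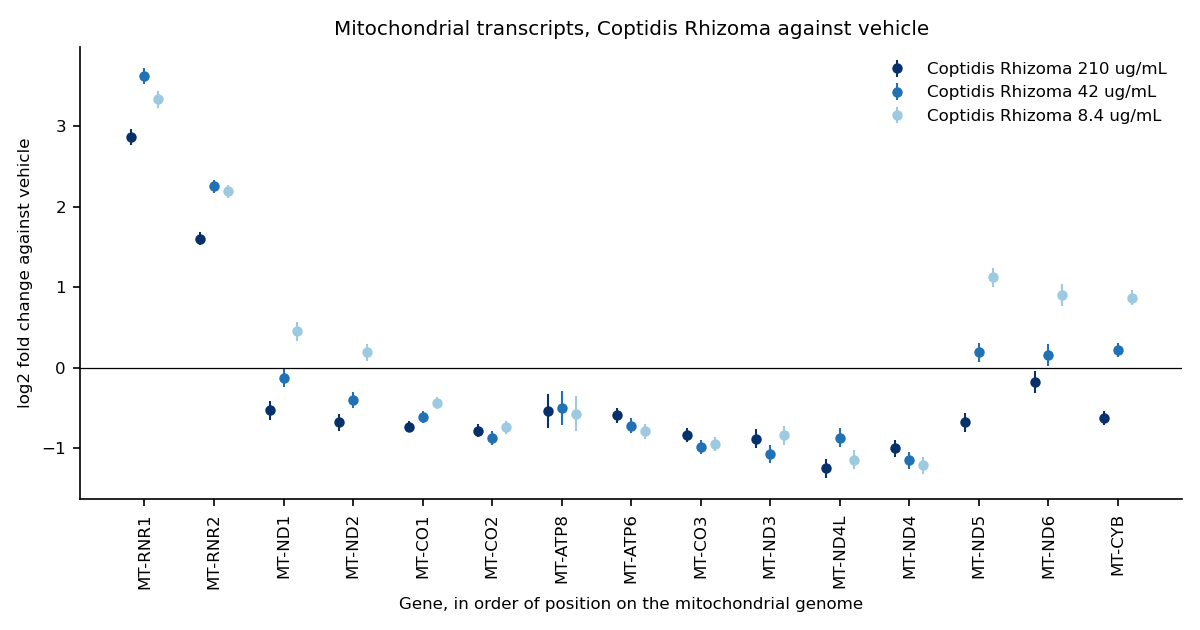
Log2 change against vehicle (with standard error) of 15 genes of the mitochondrial genome, in order of their position, for Coptidis Rhizoma at 8.4, 42 and 210 ug/mL with 3 libraries per group. MT-RNR1 lies at 3.33, 3.62 and 2.86, above all other genes shown at each dose.

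At 500 ug/mL Pinelliae Tuber and Zizyphi Fructus changed fewer genes (761 and 601) than the top doses of the other extracts (7058 or more). HAMP fell from 66.03 ± 2.15 CPM to 22.6 ± 1.12 with Pinelliae at 500 ug/mL (2.92-fold, log2 change -1.54, SE 0.071, adjusted p = 4.1e-22) and to 30.8 ± 0.749 with Zizyphi at 500 ug/mL (2.14-fold, -1.10, SE 0.068, adjusted p = 8.02e-17), with all 3 libraries of each below all vehicle libraries. SCNN1A, a subunit of the epithelial sodium channel, fell from 26.0 ± 0.762 to 14.7 ± 1.02 with Pinelliae (-0.82) and 16.9 ± 2.01 CPM with Zizyphi (-0.62), and the calcium-binding protein gene S100P fell by 0.85 and 0.66 on the log2 scale. ASNS fell by 0.40 and 0.50. With Pinelliae the fasting-induced DEPP1 (0.72) and PCK1 (0.69), the enzyme that starts glucose synthesis, rose, as did the fibrinogen chains FGA (0.33), FGB (0.26) and FGG (0.25). With Zizyphi CREB3L3 (0.47) and HMOX1 (0.32) rose.

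Metallothioneins and zinc export fell in all 8 members with Pinelliae (median -0.64, adjusted p = 3.32e-19) and in 7 with Zizyphi (-0.49, adjusted p = 2.55e-15). MT1F fell by 0.71 and 0.61, and against the bottom dose of the other extract with the same title number, itself a treated group, the values were -0.11 and -0.14. In those references MT1F was itself lower than in vehicle (53.52 to 58 CPM). It was 32.59 to 39.24 CPM at Scutellariae 20 and 37.41 to 41.4 CPM at Coptidis 8.4 ug/mL. Mitotic genes fell in 8 of 20 with each extract (medians -0.15 and -0.14, adjusted p = 5.05e-17 and 1.43e-15) and DNA replication genes in 6 of 19 (adjusted p = 1.21e-08 and 5.8e-11). HMMR fell by 0.30 with Pinelliae and by 0.25 with Zizyphi, and with Zizyphi NUSAP1 (-0.18), PCNA (-0.22), GINS2 (-0.20) and MCM6 (-0.16) fell. NUSAP1 did not pass without vehicle replicate 1 (-0.16) or replicate 1 of Zizyphi (-0.15), nor MCM6 without vehicle replicate 1 (-0.16) or 2 (-0.14) or replicate 1 (-0.16), 2 (-0.16) or 3 (-0.18) of Zizyphi. Against that other reference these 5 genes turned with Zizyphi: NUSAP1 (0.15) and GINS2 (0.16) passed the test as higher, and HMMR (0.06), PCNA (0.06) and MCM6 (0.08) did not pass. At that reference, Coptidis 8.4 ug/mL, most mitotic genes were themselves lower than in vehicle. A turn of HMMR or NUSAP1 against it may therefore come from the reference. Cholesterol synthesis fell in 9 of 25 with Pinelliae (adjusted p = 3.6e-09), with IDI1 at -0.28. The ATF4 response fell in 5 of 26 with Pinelliae (median -0.06, mean 0.05, the test pointing down, adjusted p = 4.25e-05) and in 5 of 26 with Zizyphi, where 1 rose (median -0.06, mean 0.01, the test pointing down, adjusted p = 0.000211). FOXO genes rose in 2 of 18 with each (adjusted p = 0.00716 and 0.00102), acute phase and NF-kappaB targets rose in 2 of 13 with each (adjusted p = 4.25e-05 and 0.00388) and heat shock proteins fell in 2 of 14 with Pinelliae (adjusted p = 0.00914). These calls held with an estimated correlation. Adjusted over the list alone, 17 and 16 mitotic genes, 10 and 10 replication genes and, with Pinelliae, 13 cholesterol genes fell, as did 6 and 7 ATF4 genes (1 rose with Zizyphi), while 5 and 4 FOXO genes (1 fell with Pinelliae) and 4 and 3 acute phase targets rose and 3 heat shock genes fell with Pinelliae.

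Other lists passed with the preset correlation only. With Pinelliae these were NRF2 targets, 4 of 23 higher (adjusted p = 0.236 with an estimated correlation), secreted proteins, 3 of 19 higher (adjusted p = 0.117 with an estimated correlation), and ribosomal proteins with no member called (adjusted p = 0.618 with an estimated correlation). With Zizyphi these were NRF2 targets, 6 of 23 higher (adjusted p = 0.108 with an estimated correlation), fatty acid oxidation, 4 of 16 higher (adjusted p = 0.108 with an estimated correlation), cholesterol synthesis, 1 of 25 lower (adjusted p = 0.298 with an estimated correlation), mitochondrial transcripts (adjusted p = 0.321 with an estimated correlation), autophagy (adjusted p = 0.108 with an estimated correlation) and ribosomal proteins (adjusted p = 0.576 with an estimated correlation).

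The counts for these extracts at 500 ug/mL depended on the libraries and the setting used. Here too, fewer libraries alone can lower a count. Pinelliae gave 761 genes (439 higher), and 1340 without the 3 libraries that stand apart, none of which is in the groups compared. Pinelliae gave 361 or 298 without vehicle replicate 1 or 2 and 435, 1163 or 201 without its own replicate 1, 2 or 3. Zizyphi gave 601 genes (347 higher), 1637 in a fit of only the 2 groups, and 256 or 182 without vehicle replicate 1 or 2 and 293, 324 or 243 without its own replicate 1, 2 or 3. At 100 ug/mL HAMP fell by 0.55 and the glutamate transporter gene SLC1A2 by 0.50 with Pinelliae, among 34 genes (4 in a fit of only the 2 groups and 333 with no filter on low counts; 8, 9 or 7 without vehicle replicate 1, 2 or 3, and 17 or 14 without its own replicate 2 or 3, of which replicate 3 stood apart at a mean chi-square of 17.3 to 17.4). With Zizyphi ASNS fell by 0.52 (adjusted p = 4.09e-08) and the kisspeptin receptor gene KISS1R rose by 0.97, among 38 genes (431 in a fit of only the 2 groups and 434 with no filter; 4, 8 or 8 without vehicle replicate 1, 2 or 3, and 22, 8 or 8 without its own replicate 1, 2 or 3). No list call at 100 ug/mL of either extract held with an estimated correlation.

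At 20 ug/mL of Pinelliae 1 gene was called, KISS1R (0.96), and 264 in a fit of only the 2 groups. With edgeR this count became 0 without any of the 3 vehicle libraries or the extract's replicate 1, and 2 without its replicate 3; 1153 genes had an unadjusted p under 0.05 and DESeq2 called 3 (66.7% higher). Zizyphi at 20 ug/mL gave 331 genes (61.6% higher), but with edgeR 0 in a fit of only the 2 groups (2937 had an unadjusted p under 0.05 in all libraries, and DESeq2 called 650, 50.2% higher). It gave 858 with no filter on low counts (66.7% higher), and 16, 56 or 140 without vehicle replicate 1, 2 or 3 and 62, 106 or 2242 without its own replicate 1, 2 or 3, of which replicate 1 stood apart at a mean chi-square of 18.5 to 39.1. Ribosomal proteins rose in 1 of 21 (adjusted p = 4.55e-05, and adjusted p = 0.741 with an estimated correlation).

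Top and bottom doses of an extract share a title number and were compared to show what dose changes. HAMP fell by 1.29 on the log2 scale with Pinelliae, by 1.09 with Zizyphi and by 3.72 with Scutellariae. With Pinelliae ID1, a target of bone morphogenetic protein (BMP) signalling, fell by 0.76 and S100P by 0.78, and PCK1 (0.80) and CYP1A1 (0.90) rose. IGFBP1 rose by 3.68 with fresh and 3.80 with dried ginger, MT1F fell by 2.84 and 2.91, and FOS rose by 4.71 and 3.96. With Scutellariae MMP3 (5.36) and the complement receptor C5AR1 (4.85) rose, and with Coptidis C5AR2 rose by 7.09. The counts were 10948 genes for Coptidis, 8308 for Scutellariae, 7997 for fresh and 6815 for dried ginger. Zizyphi gave 1201, 2 in a fit of only the 2 groups, and 772, 436 or 694 without replicate 1, 2 or 3 at 500 ug/mL and 215 or 3322 without replicate 1 or 3 at 20 ug/mL. Pinelliae gave 316, 151 in a fit of only the 2 groups, and 148 without replicate 3 at 500 ug/mL and 64 or 118 without replicate 1 or 3 at 20 ug/mL.

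These comparisons share no libraries, so their overlap can be read without shared controls. Fresh and dried ginger shared 2929 higher genes (849 for independent lists) and 2671 lower genes (789), with a Pearson correlation of 0.94 across 9853 genes, which are not independent replicates. Scutellariae and Coptidis shared 3129 higher (1346) and 3193 lower genes (1387), with a correlation across genes of 0.80. Fresh ginger and Coptidis shared 3153 higher (1340) and 3054 lower genes (1291), also at 0.80. Pinelliae and Zizyphi shared 125 higher (9) and 68 lower genes (3), HAMP among them, at 0.50. In edgeR fits of only the 2 groups compared, the Zizyphi list held 2 genes, both lower and shared with Pinelliae, HAMP among them, whereas DESeq2 on all libraries shared 158 higher and 102 lower genes. With no filter on low counts 104 lower genes were shared. The numbers for independent lists assume that every gene is equally likely to be called, which was not tested. Of the genes higher with Pinelliae, 84 were higher (66 for independent lists) and 103 lower (65) with Coptidis. Pinelliae and Zizyphi had 0 genes called in opposite directions (6 and 5).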

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

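The test and its alternatives were chosen after seeing the data, and the genes named after their values were seen. The change from 20 to 500 ug/mL differed between fresh and dried ginger for 109 genes (edgeR quasi-likelihood test of the difference itself), 60 with a higher and 49 with a lower change in fresh ginger, and 2162 genes had an unadjusted p under 0.05. The count was 9 in a fit of the 4 groups alone and 67 without the libraries that stand apart. Which direction held more genes depended on the setting, with 50 higher and 50 lower with RLE size factors, 138 and 230 with no filter, and 143 and 129 with DESeq2. It was 27, 397 or 185 without replicate 1 (which stands apart), 2 or 3 of dried ginger 500 ug/mL, 50 or 53 without replicate 1 or 3 of fresh ginger 500, 39, 165 or 48 without replicate 1, 2 or 3 of fresh ginger 20, and 68, 48 or 71 of dried ginger 20 ug/mL. The ubiquitin-like UBD moved by -0.02 with fresh and by 0.74 with dried ginger (difference -0.76, adjusted p = 1.97e-07), and the NF-kappaB feedback genes TNFAIP3 (-0.51) and NFKBIA (-0.37) and the surface protein gene CD83 (-1.16) also rose less, or fell more, with fresh ginger. The amino acid response genes ASNS (1.22 with fresh and 0.72 with dried ginger) and SLC7A11 (difference 0.48) rose more with fresh ginger. The lipid droplet gene PLIN2 (0.42), the growth regulator ARRDC3 (0.51) and the zinc exporter SLC30A1 (0.34) had a higher change with fresh ginger, and the mitotic kinases AURKB (-0.33) and PLK1 (-0.30) a lower one. In the fit of the 4 groups alone NFKBIA, CD83, PLIN2, SLC30A1, AURKB and PLK1 did not pass the test, nor did NFKBIA (-0.31) and CD83 (-1.10) without dried ginger 500 replicate 1, nor CD83 (-0.99) without fresh ginger 20 replicate 1. The other genes named passed under each alternative.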

How the results depend on the processing

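Leaving out the 3 libraries that stand apart, and each alternative for the difference between the dose changes of fresh and dried ginger and for the genes shared by Pinelliae and Zizyphi, was chosen after seeing the data; the others were planned. Where a count of called genes changed, the cause was not tested, except where the construction of an alternative shows it. A fit of only the groups compared also replaces the spread shared by all groups with their own, so its counts can rise or fall. RLE size factors kept all 28 counts within 1.5 times and left all 586 values of named genes on their side of the threshold. Without the 3 libraries that stand apart, the counts became 1798 for fresh ginger 20 ug/mL, 49 for dried ginger 20, 1340 for Pinelliae 500, 49 for Pinelliae 20, 1197 for Scutellariae 20, 1237 for Zizyphi 500, 364 for Zizyphi 100, 548 for Pinelliae and 367 for Zizyphi top against bottom dose, and 115 and 28 for fresh against dried ginger at 100 and 20 ug/mL. Of these comparisons only Zizyphi top against bottom dose includes any of those libraries. The other counts changed through the filter, scaling and spread that all libraries share. With no filter on low counts, more genes were tested, and the counts became 255 for dried ginger 20, 333 for Pinelliae 100, 241 for Pinelliae 20, 434 for Zizyphi 100, 858 for Zizyphi 20 and 501, 178 and 179 for fresh against dried ginger at 500, 100 and 20 ug/mL. A fit of only the 2 groups compared, which estimates the spread from fewer libraries, gave 322 for dried ginger 20, 4 for Pinelliae 100, 264 for Pinelliae 20, 1637 for Zizyphi 500, 431 for Zizyphi 100, 0 for Zizyphi 20 (2937 genes had an unadjusted p under 0.05 in all libraries with edgeR, and DESeq2 called 650), 151 for Pinelliae and 2 for Zizyphi top against bottom, and 29, 115 and 0 for fresh against dried ginger at 500, 100 and 20 ug/mL (at 20, 1417 at an unadjusted p under 0.05 with edgeR and 13 with DESeq2). DESeq2 gave 98 for Pinelliae 100, 3 for Pinelliae 20, 141 for Zizyphi 100, 650 for Zizyphi 20, and 96 and 13 for fresh against dried ginger at 100 and 20 ug/mL.

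Leaving out each library in turn gave 70 to 991 genes for fresh ginger 20, 6 to 10 for dried ginger 20, 201 to 1163 for Pinelliae 500, 7 to 31 for Pinelliae 100, 0 to 2 for Pinelliae 20 (with edgeR; 1153 at an unadjusted p under 0.05 in all libraries and 3 by DESeq2), 410 to 588 for Scutellariae 20, 182 to 474 for Zizyphi 500, 4 to 22 for Zizyphi 100 and 16 to 2242 for Zizyphi 20. It gave 64 to 408 for Pinelliae and 215 to 3322 for Zizyphi top against bottom dose, and 158 to 605, 28 to 51 and 0 to 26 for fresh against dried ginger at 500, 100 and 20 ug/mL. The count for the difference between the dose changes of fresh and dried ginger, 109, became 27 to 397 with a library left out, 67 without the 3 libraries apart, 9 in a fit of the 4 groups, 368 with no filter and 272 with DESeq2. Its balance of higher and lower genes also depended on the setting. In all, 101 of 166 counts against vehicle, between doses or between gingers with a library left out stayed within 1.5 times. Of 3505 values of named genes with a library left out, 367 lost their call, 2 gained one and 3 reversed, none of the 3 a called change. The reversed values were with Pinelliae 500, for DDIT3 (0.01 without its replicate 3, range -0.11 to 0.01), IRS2 (-0.62 without its replicate 3, range -0.62 to 0.54) and ALB (-0.01 without its replicate 2, range -0.01 to 0.07).

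With the bottom dose of the other extract of the same title number as the reference, the count was 2063 for Pinelliae 500 and 2261 for Zizyphi 500. That reference is itself a treated group (Scutellariae 20 or Coptidis 8.4 ug/mL), in which CYP1A1 and the NRF2 targets were higher and MT1F lower than in vehicle. At Coptidis 8.4 ug/mL most mitotic genes were also lower. The reference therefore adds its own changes. Of 361 values 293 kept their call and direction, 36 lost and 8 gained a call, and 24 reversed. The reversed values were -0.07 for DDIT3 with dried ginger 500 and 0.06 for TGIF2-RAB5IF with Scutellariae 500. With Pinelliae 500 they were -3.81 for CYP1A1, 0.07 for MT1M, -0.20 for HMOX1, -0.14 for ABCC2, -0.09 for SQSTM1, 0.01 for DDIT3, -0.18 for IRS2 and -0.27 for IGFBP1. With Zizyphi 500 they were -0.14 for TIE1, -0.02 for TYMP, -0.08 for DEPP1, -0.44 for SQSTM1, -0.66 for IGFBP1, 0.06 for HMMR, 0.15 for NUSAP1, 0.06 for PCNA, 0.16 for GINS2, 0.08 for MCM6, -0.16 for ICAM1, -2.18 for CYP1A1, -0.54 for TRIB3 and 0.15 for ALB.

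With the replicate number as a block, 27 of 28 counts stayed within 1.5 times and Pinelliae 20 gave 0 in place of 1 (edgeR; DESeq2 without a block called 3, and 1153 genes had an unadjusted p under 0.05 without it). Apart from Scutellariae top against bottom dose the correlations of same-numbered libraries were not all over 0.1, which cannot show that pairing is absent. They were 0.02 to 0.335 for Zizyphi top against bottom dose and 0.018 to 0.296 for Pinelliae 500 against vehicle. For Coptidis 210 against vehicle they were -0.216 to -0.057. Of 586 named gene values 1 lost and 0 gained a call under the block. Of 700 list tests 1 lost its call, ribosomal proteins of Pinelliae top against bottom dose, and 6 gained one. An estimated correlation in camera ended 96 of 700 list results, and RLE size factors added 1. Among named genes, no filter ended 10 of 586 calls, DESeq2 7 of 532, a fit of only the 2 groups 41 of 576 and leaving out the 3 libraries apart 13 of 586. Depth limits the genes with few counts, whose folds are given as bounds or with counting intervals.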

Other observations

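The genes and tests of the zinc genes, the mitochondrial ribosomal RNA against another group of the same title number, depth, transcript length and GC content in the libraries apart, and HAMP against the bottom dose were chosen after the result was seen. SLC30A1, the zinc exporter of the cell surface and a member of the list with the metallothioneins, fell with fresh ginger by 0.63, 0.92 and 0.32 on the log2 scale at 500, 100 and 20 ug/mL, and with dried ginger by 0.84, 0.89 and 0.19. The importer SLC39A10 rose by 1.65, 1.27 and 0.30 with fresh and by 1.57, 1.22 and 0.46 with dried ginger, and SLC39A4 rose by 0.69, 0.74 and 0.40 with fresh and by 0.74, 0.74 and 0.31 with dried ginger. With Coptidis SLC39A10 rose by 1.81 at 210 and 1.39 at 42 ug/mL while SLC30A1 fell by 0.38 at 42 ug/mL and did not pass the test at 210 ug/mL (-0.08). With Scutellariae at 500 ug/mL SLC39A10 rose by 1.14 and SLC30A1 fell by 0.23.

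Besides Pinelliae, Zizyphi and Scutellariae, HAMP fell with fresh ginger by 1.65 and with dried ginger by 1.91 on the log2 scale at 500 ug/mL, and by 0.50 and 0.83 at 100 ug/mL, and with Coptidis by 0.36 at 42 and 0.27 at 8.4 ug/mL, but did not pass the test at 210 ug/mL (-0.06). It fell by 0.25 with wortmannin. At Scutellariae 500 ug/mL the BMP targets ID1 (-1.34), ID2 (-1.06), ID3 (-1.21), SMAD6 (-1.22), SMAD7 (-0.92), SMAD9 (-1.63) and ATOH8 (-1.26) fell, and BAMBI did not pass (-0.15). At Coptidis 210 ug/mL ID1 (0.42), ID2 (1.07), ID3 (0.39), SMAD7 (0.93), BAMBI (0.32) and ATOH8 (2.82) rose, whereas SMAD6 (-0.27) and SMAD9 (-0.60) fell. At Coptidis 42 ug/mL, where HAMP fell, ID1 (0.43), ID2 (0.16), BAMBI (0.41) and ATOH8 (0.87) rose and SMAD9 (-0.22) fell.

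HAMP was lower at 500 ug/mL of Pinelliae and Zizyphi than in vehicle. Chance values of the shared vehicle libraries are argued against, since HAMP also fell against the bottom dose of the same extract, by 1.29 and, for the smaller fall, with a log2 change of -1.09. As a hypothesis, lower BMP-SMAD signalling may go with the lower HAMP: of ID2, ID3, SMAD6, SMAD7, SMAD9 and BAMBI, 6 of 6 were called lower with Pinelliae and 4 of 6 with Zizyphi. SMAD6 (-0.18), BAMBI (-0.15) and ID1 (-0.18) did not pass with Zizyphi, and at 100 ug/mL HAMP fell with Pinelliae (-0.55), fresh (-0.50) and dried ginger (-0.83) while the 6 genes counted above did not pass the test (-0.21 to -0.03 with Pinelliae, -0.09 to 0.13 with fresh ginger) except ID2 with dried ginger (-0.15), and ATOH8 rose with fresh ginger (0.65). For the gingers at 500 ug/mL, where HAMP also fell, the BMP target genes are not reported here, so the hypothesis was not compared with them. HAMP and these genes come from the same libraries, and no protein or signalling measurement was analysed here.

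MT-RNR1 was 10.1-fold higher at 8.4 ug/mL of Coptidis than in vehicle. A difference between sets of libraries with the same title number is argued against, since MT-RNR1 at Zizyphi 20 ug/mL, of the same number, had a log2 change of 0.08 (SE 0.095). Reads shared with nuclear copies of the mitochondrial genome are argued against, since the 404 annotated copies together held 927 CPM in vehicle and 727 CPM at 8.4 ug/mL, whereas MT-RNR1 gained 37600 CPM. The replication-dependent histones showed no rise that would point to more RNA without poly(A) tails (median -0.16, quartiles -0.26 and -0.07). They cannot exclude it, since these genes also follow DNA replication, and mitotic genes fell at this dose. An effect of the extract on mitochondrial transcripts may remain, as a hypothesis found and tested on the same data. A higher MT-RNR1 was not confined to Coptidis, although the gingers rose less. At the top dose it was 6765 to 7357 CPM with fresh and 7138 to 11870 CPM with dried ginger. At the middle dose it was 7056 to 8188 and 7801 to 7887 CPM, against 3952 to 4265 CPM in vehicle. The highest value came from the dried ginger library that stood apart. The authors' counting of mitochondrial ribosomal RNA was not tested.

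Replicate 1 of dried ginger 500 ug/mL, replicate 3 of Pinelliae 100 ug/mL and replicate 1 of Zizyphi 20 ug/mL stood apart from the other libraries of their groups, with the same treatment in the labels, and no biological explanation was tested. Lower depth is argued against in dried ginger, since the 10 libraries of other groups with totals as low, also relative to their own group, had lowest mean chi-square values of at most 4.627 against 15.064. In Pinelliae and Zizyphi, with 21582603 and 21603198 counts, the lowest totals of the 59 libraries, no library of another group was as low. Sampling noise from lower depth is argued against there too, since it would leave the chi-square near 1 at any depth, against 17.321 and 18.532. Other differences that go with low depth cannot be told apart there. A trend with transcript length may contribute in Pinelliae, where the difference of replicate 3 from each other library had a rank correlation across genes with length of at least 0.547 in size, beyond the 49 pairs of groups without such a library (at most 0.413), while the other pair had 0.054, and GC content is argued against there (at most 0.074 in size). In Zizyphi a length trend of replicate 1 (at least 0.518 in size) cannot be told apart from one of replicate 3, since replicate 2 minus 3 also had -0.492, and length in dried ginger (-0.357 and 0.186 in size) and GC content in Zizyphi (-0.103 and 0.036 in size) and dried ginger (0.44 and 0.452) lay within the sizes of the 49 pairs (at most 0.413 and 0.578) and cannot be told apart from other sources. Length and GC content were those of the longest annotated transcript of each gene, which need not be the one expressed. With smooth trends on both removed, the spread (SD) across genes of the log2 difference was at least 0.146 in pairs with the 3 libraries. It was 0.087 to 0.117 in the 49 pairs, although Zizyphi replicates 2 and 3 also gave 0.137. Smooth trends with these measures are therefore argued against as the whole cause. A bias that these measures capture only in part is not.

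The 6 libraries of a comparison of 3 with 3 can be split in 10 ways, so a share under 0.05 cannot be reached. Every other split mixes libraries of both groups, so that a real difference becomes spread within its parts. Low counts in the other splits are therefore no measure of false calls. In fits of the 6 libraries alone, the real groups of wortmannin and vehicle called 6681 genes, and the highest of the other splits 0. Against vehicle, the real and highest other counts were 7998 and 0, 4461 and 0, and 1220 and 1 for fresh ginger at 500, 100 and 20 ug/mL, and 6102 and 0, 3964 and 0, and 322 and 4 for dried ginger. They were 621 and 3 and then 4 and 0 for Pinelliae at 500 and 100 ug/mL, and 8859 and 0, 2976 and 0, and 903 and 1 for Scutellariae. They were 11410 and 0, 8353 and 0, and 3158 and 2 for Coptidis at 210, 42 and 8.4 ug/mL. Zizyphi gave 1637 and 0, 431 and 1, and 0 and 0. For the top against the bottom dose they were 7856 and 0 for fresh and 5875 and 0 for dried ginger, 8412 and 0 for Scutellariae, 10573 and 0 for Coptidis and 2 and 2 for Zizyphi. For fresh against dried ginger they were 29 and 0 at 500, 115 and 3 at 100, and 0 and 40 at 20 ug/mL. The number of splits with a count as large as the real one, itself included, was 1 in each comparison except Zizyphi top against bottom (2), Zizyphi 20 ug/mL (10) and fresh against dried ginger at 20 ug/mL (10). In the last, a split that called 40 genes where the groups called 0 points to a structure of the samples, which was not tested. The counts of 0 for the real groups are from edgeR with the groups compared alone. In the model of all libraries edgeR called 331 genes for Zizyphi 20 ug/mL (2937 at an unadjusted p under 0.05, 650 by DESeq2) and 8 for fresh against dried ginger at 20 ug/mL (1417 and 13).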
